A study of Mus musculus with 10 samples.

How the data were processed

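RNA was extracted from frozen left ventricle with TRIzol, purified on spin columns and prepared with an Illumina TruSeq RNA kit, per the labels' protocols; whether the libraries keep strand is not given in the sources used here. The authors deposited a table of estimated (expected) counts from RSEM, 1 value per Ensembl mouse gene and library, not scaled to a common total. The submitters' processing notes name cutadapt, RSEM 1.17, Picard and limma, without roles or order. The aligner, genome build and annotation release are not given in the sources used here. Of the deposited expected counts 23.0% were not whole numbers, and all were rounded before testing, which changed a library total by at most 0.000387%. The table held 35808 genes, of which 10844 had no count in any library.

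Libraries were placed in groups by the labels. The columns of the table carry library numbers, not sample titles. Each label gives a barcode sequence, and from general knowledge of Illumina's TruSeq adapter numbering the barcodes, in ascending order of adapter, match the library numbers, with the unused numbers falling at the adapters no label carries. The 8 columns so matched to heteroplasmic samples share a letter code that no other column has. Which of the remaining columns is C57 and which is NZB rests on this numbering alone. A chi-square comparison of all 45 pairs of libraries gave 7.54 to 100 per gene, so each pair differed by more than sampling noise and each library was counted once.

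Gene symbols were taken from a table of Ensembl IDs, and positions and the length and GC content of the longest transcript from GENCODE M21 on GRCm38, both matched by Ensembl ID (35469 of 35808 IDs matched). The build behind the deposited counts is not given in the sources used here, so positions describe the annotated gene and not the authors' own coordinates. Of the tested genes, 58 had no length.

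Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr on the 2 groups (16136 genes kept), glmQLFit with robust dispersion and glmQLFTest, with Benjamini-Hochberg adjustment at 0.05. The main contrast set the 8 heteroplasmic against both conplastic libraries together. A second fit with 3 genotypes gave heteroplasmic minus C57 and heteroplasmic minus NZB, where the spread comes from the heteroplasmic libraries alone. Standard errors are the log2 fold change divided by the square root of F. CPM values are counts scaled to the TMM-adjusted size of each library, and log2 CPM used a prior count of 2. The NZB and C57 libraries were compared by size only, requiring a log2 ratio beyond 1, beyond the range of the 8 heteroplasmic libraries, and a mean CPM of at least 5.

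The gene lists and the rule for the genes named in the text were fixed before the data were examined. Of 53 lists, 52 had at least 5 tested members. They were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, which asks whether genes of a list move one way. With the preset correlation 21 lists passed, 5 higher and 16 lower; with an estimated correlation 0 passed, the smallest adjusted p among the 21 being 0.316. By fry, 15 of the 21 had an adjusted p under 0.05. In the alternative settings, such as a library left out or trends removed, camera was run with the preset correlation only. Its adjusted p there may be too small for lists whose genes vary together.

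Part A of the rule took the 12 highest and 12 lowest fold changes among genes past the main test with a mean CPM of at least 5 and all heteroplasmic libraries on one side of both conplastic libraries. Part B took up to 4 members per list by p, part C the 5 highest and 5 lowest against each conplastic library, part D the 8 largest ratios of NZB to C57, and part E the 13 protein genes of mtDNA and checks of background and sex. Gene models without a proper symbol and pseudogenes were passed over in parts A, C and D. Some genes that the rule names are not reported here. Rps12-ps3 was named after its values were seen.

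The steps were tested on simulated counts for the 16136 genes with 200 genes changed, in 5 runs. For heteroplasmic versus conplastic, 23.2% of genes changed 1.25-fold, 71.2% of those changed 1.5-fold and 95.6% of those changed 2-fold were recovered. Of all calls there 4.50% were false. For heteroplasmic versus C57 the shares recovered were 5.6%, 39.2% and 83.6%, with 6% of calls false. For heteroplasmic versus NZB they were 4.8%, 45.6% and 86.8%, with 3.48% false. The simulated genes varied independently, without a length trend, and both conplastic libraries were shifted alike in the pooled contrast. Each lone library was given the same spread as the others. The shares of false calls therefore hold for such simpler counts and not for these data. Alternatives were DESeq2 1.42.0 and its size factors, limma voom, no low-count filter, library sizes without mtDNA genes, dispersion without robust fitting, unrounded counts, a test against a 1.5-fold change, a contrast with the mean of both conplastic genotypes, other floors for the size rule and leaving out each library. Chosen after seeing the data were the removal of per-library lowess trends on transcript length and GC content, as offsets, and leaving out heteroplasmic libraries 1 and 5, which hold the most reads of Mmrn1. The C57 library had the fewest counts, 29380653, and the effect of depth was not tested. Figures were drawn with matplotlib 3.10.9.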

Results

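The left ventricle of 12-week-old male mice was profiled by RNA-seq in 10 libraries that shared a C57BL/6JOlaHsd nuclear genome and differed in mitochondrial DNA (mtDNA). A single library came from the conplastic strain with C57 mtDNA, a single library from the conplastic strain with NZB mtDNA, and 8 libraries from heteroplasmic mice, which carry both mtDNA types after fusion of embryos. The conplastic strains share a nuclear genome and differ in the source of their mtDNA. The design sets conplastic against heteroplasmic hearts, asking which transcripts differ when normal mtDNA variants are mixed. Estimated counts summed to 29380653 in the C57 library, 44157810 in the NZB library and 35550580 to 87814909 in the heteroplasmic libraries. Transcripts of mtDNA took 36.1% of the counts in the C57 library, 40.005% in the NZB library and 38.3% ± 1.09 (SD, n = 8) in the heteroplasmic libraries. Across the 16136 tested genes, which are not independent replicates, Pearson's r of log2 counts between heteroplasmic libraries ran from 0.986 to 0.993, and between the C57 and NZB libraries it was 0.981. The median r with the heteroplasmic libraries was 0.985 for the C57 and 0.984 for the NZB library, both above the value between the conplastic libraries. The labels do not say that the 8 heteroplasmic libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. In the main contrast the spread of the conplastic group also includes the difference between the C57 and NZB libraries.

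Genes induced by interferon and genes of antigen presentation were lower in heteroplasmic hearts than in the conplastic hearts. Of 28 measured genes of the interferon list 19 fell and none rose (26 fell adjusted over the list alone), and of 17 antigen-presentation genes 15 fell and none rose (17 fell adjusted over the list alone). The median log2 fold change was -0.62 for the interferon list and -0.75 for the antigen-presentation list. Against the C57 library the medians were -0.43 and -0.59, and against the NZB library -0.72 and -0.88. Camera, which compares a list with all other genes, gave adjusted p = 5.36e-19 and 1.09e-14 with a preset correlation, and adjusted p = 0.316 for both lists with an estimated correlation. Single calls leaned on the NZB library: without it most interferon genes and all antigen-presentation genes missed the threshold. In that fit the C57 library stood alone on the conplastic side, and the list medians were -0.43 and -0.59. Without heteroplasmic libraries 4, 5 and 6 in turn 9, 12 and 10 interferon genes passed, without libraries 4 and 6 in turn 7 and 8 antigen-presentation genes, and with libraries 1 and 5 both omitted 9 and 7. With trends on transcript length and GC content removed, a setting chosen after seeing the data, 11 and 12 passed.

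Several of the genes with the largest falls encode GTPases of cell-autonomous defence. Igtp was at 14.1 ± 3.66 CPM (SD, n = 8) in heteroplasmic hearts against 28.7 in the C57 and 49.2 in the NZB library, a log2 fold change of -1.48 ± 0.26 (SE, edgeR adjusted p = 0.0289). Its list also holds Iigp1 at -1.33 and Gbp3 at -1.10. Tgtp2, Gbp4 and Irgm2, which are not on the list, had values of -1.56, -1.33 and -1.18. Igtp and Irgm2 overlap on chromosome 11 of GRCm38 (58199556 to 58207591 and 58199618 to 58222782) and Tgtp2 has a near-identical copy, so the division of reads among them is uncertain. With those trends removed Tgtp2, Gbp4 and Iigp1 missed the threshold at log2 fold changes of -1.49, -1.34 and -1.27 (adjusted p = 0.0594, 0.0598 and 0.0699).

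The antiviral genes Ifit3, Bst2 and Rsad2 fell, with log2 fold changes of -0.80, -0.63 and -0.65. B2m, the light chain of class I molecules (chromosome 2, 122147686 to 122153083), was at 163 ± 19.96 CPM (SD, n = 8) against 274 in the C57 and 330 in the NZB library, a log2 fold change of -0.89 ± 0.11 (edgeR adjusted p = 0.00635). The class I chain H2-D1 stood at -0.67, the class II chain H2-Aa at -0.80, the peptide transporter Tap1 at -1.05, the immunoproteasome subunits Psmb8 and Psmb9 at -0.92 and -1.05, and the class I transactivator Nlrc5 at -1.20. The annotated spans of Tap1 and Psmb9 overlap, so their split of reads is uncertain. The chemokine Cxcl9 was at 5.47 ± 1.21 CPM against 12.0 and 11.7. For each gene of this and the preceding paragraph, all 8 heteroplasmic libraries lay below both conplastic libraries. Without the NZB library Ifit3 and Rsad2 passed (adjusted p = 0.0477 and 0.0367), and Bst2 and B2m did not (adjusted p = 0.0732 and 0.0689).

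**Figure D1:**
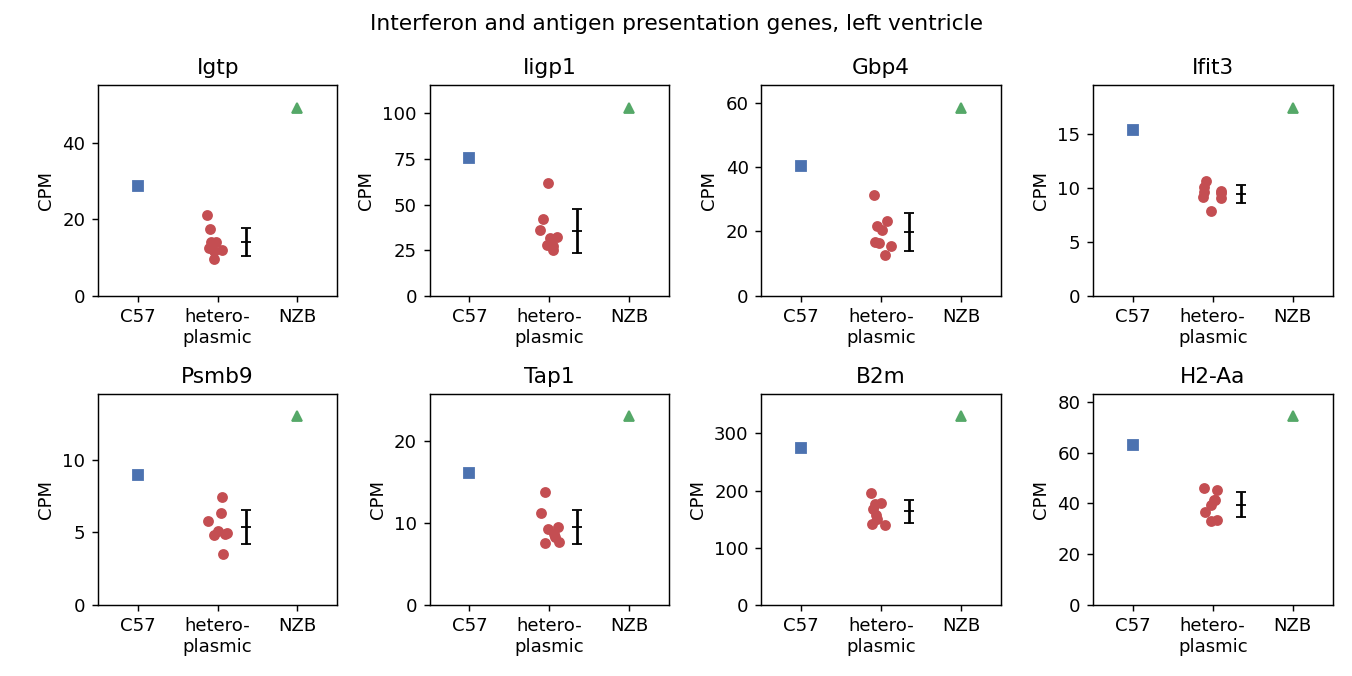
CPM of 8 interferon and antigen-presentation genes in each library (C57 square, heteroplasmic circles with mean and SD, NZB triangle; linear axes from 0). In every panel the 8 heteroplasmic libraries lie below both conplastic libraries.

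Markers of lymphocytes and macrophages were lower as well. Of 17 lymphocyte markers 2 fell (5 adjusted over the list alone), the granzyme gene Gzma at -1.59 and the T cell receptor chain Cd3e at -1.81, both under 2 CPM in every library, and the list median was -0.50. Of 15 macrophage markers 2 fell (7 adjusted over the list alone), Aif1 at -0.95 and Cd68 at -0.51, and the median was -0.29. Adjusted p was 3.33e-06 for the lymphocyte and 4.94e-06 for the macrophage list, and adjusted p = 0.316 and 0.330 with an estimated correlation. Without the C57 library the macrophage list gave adjusted p = 0.0906 and a median of -0.15, and without the NZB library its median was -0.50. No lymphocyte, macrophage or endothelial marker passed without the NZB library. Of 17 endothelial markers 2 fell, Emcn and Fabp4 (2 adjusted over the list alone; adjusted p = 0.00670, and adjusted p = 0.402 with an estimated correlation), and the list gave adjusted p = 0.0562 without the C57 and 0.0516 without the NZB library. Of 6 neutrophil markers none passed, over all genes or over the list alone, and their median was 0.83 (adjusted p = 0.516), or 0.24 without heteroplasmic library 8.

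Genes of the cytosolic ribosome and nuclear genes of respiratory complexes I, III, IV and V were lower by smaller amounts. Of 53 ribosomal protein genes on the list 24 fell and none rose (45 fell adjusted over the list alone), with a median of -0.22, and Rpl24 and Rpl14 stood at -0.38 ± 0.06 and -0.29 ± 0.06. Of 36 complex I subunits 13 fell (25 adjusted over the list alone), among them Ndufb2 at -0.36. Of 16 complex V subunits 5 fell (11 adjusted over the list alone), among them Atp5j and Atp5o at -0.30 and -0.26. Of 22 complex IV genes 5 fell (13 fell and 2 rose adjusted over the list alone), among them Cox7a2 and Cox5b at -0.29 and -0.25, and of 10 complex III genes 3 fell (4 adjusted over the list alone), among them Uqcrh at -0.25. Of 6 complex II genes none passed, over all genes or over the list alone, and their median was -0.07 (adjusted p = 0.442). Of 31 proteasome genes 2 fell (16 adjusted over the list alone), among them Psma3 at -0.22, and of 58 mitochondrial ribosome genes 1 fell (1 adjusted over the list alone). Camera gave adjusted p = 3.32e-23 for the cytosolic ribosome, 3.99e-13, 1.59e-06, 0.000334 and 0.00259 for complexes I, V, IV and III, 3.91e-06 for the proteasome and 7.37e-05 for the mitochondrial ribosome. With an estimated correlation, the cytosolic ribosome and complex V had adjusted p = 0.316 and the others adjusted p = 0.330.

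These transcripts are mostly short, and fold changes tracked transcript length (Spearman's rho = 0.344 across 16078 genes, which are not independent replicates). They tracked GC content less (rho = 0.051). Within the heteroplasmic group, however, rho of log2 CPM deviations with GC content ran from -0.25 in library 2 to 0.35 in library 6. In the C57 and NZB libraries it was -0.08 and 0.0006. With length and GC trends removed, 1 cytosolic ribosome, 1 complex I and 1 complex V gene passed, and the medians of these lists went from -0.22, -0.21 and -0.20 to -0.10, -0.08 and -0.09. The lists of complex III, complex IV, the proteasome and the mitochondrial ribosome then gave adjusted p = 0.284, 0.408, 0.320 and 0.479, and the cytosolic ribosome, complex I and complex V gave adjusted p = 9.99e-11, 0.000185 and 0.00225. Leaving out the NZB library moved the medians of the cytosolic ribosome and complexes I, III, IV and V from -0.22, -0.21, -0.14, -0.17 and -0.20 to -0.16, -0.13, -0.09, -0.11 and -0.14. Those of the proteasome and the mitochondrial ribosome went from -0.14 and -0.09 to -0.09 and -0.05. Without the NZB library the genes of the cytosolic ribosome, complex I, III, IV and V, proteasome and mitochondrial ribosome lists all missed the threshold. That fit leaves the C57 library alone on the conplastic side. Without heteroplasmic libraries 2, 4, 5, 6, 7 and 8 in turn 15, 2, 6, 3, 10 and 11 cytosolic ribosome genes passed, and without libraries 2 to 8 in turn 6, 8, 3, 3, 3, 4 and 8 complex I genes. Complex IV had 0 genes past the test without library 4, 5, 6 or 7, complex III without library 4 or 6, complex V without library 4, and the proteasome without any 1 of libraries 2 to 8. With libraries 1 and 5 both omitted 1 cytosolic ribosome, 2 complex I, 0 complex III, 0 complex IV and 0 complex V genes passed. Camera with the preset correlation gave these lists adjusted p = 2.71e-20, 5.47e-12, 0.00421, 0.000700 and 6.77e-06, and an estimated correlation was not run there.

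**Figure D2:**
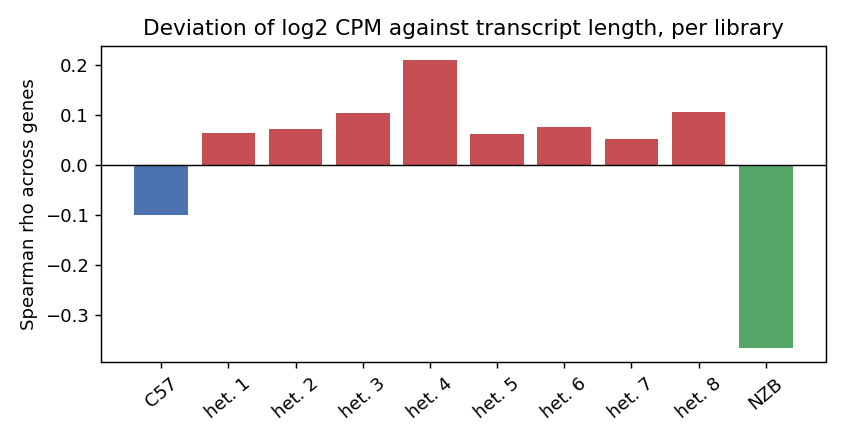
Spearman's rho across genes between transcript length and the deviation of log2 CPM from the mean of the 10 libraries, 1 bar per library. The NZB library stands at -0.37 and the C57 library at -0.10, and the 8 heteroplasmic libraries lie between 0.05 and 0.21.

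Lists of insulin signalling, hypertrophy and calcium handling had higher medians, at 0.27, 0.16 and 0.11. Against the C57 library the medians were 0.13, 0.20 and 0.003, and against the NZB library 0.37, 0.25 and 0.24. Of 20 insulin and growth factor genes 2 rose and 1 fell (10 rose and 1 fell adjusted over the list alone): Tsc1 and Rptor, a brake and a subunit of the mTOR pathway, at 0.40 and 0.35, and the growth factor Igf1 at -0.47. That list had adjusted p = 0.000202, and adjusted p = 0.402 with an estimated correlation, and without the NZB library 0.321. Without the C57 library 12 of its genes rose, and without the NZB library or heteroplasmic library 4 none did. Of 20 hypertrophy genes Mybpc3 and Xirp2 rose at 0.41 and 0.55 (4 rose adjusted over the list alone; adjusted p = 0.00436, and adjusted p = 0.330 with an estimated correlation), and the list gave 0.213 without the NZB library. Of 28 calcium and ion channel genes 1 rose (1 adjusted over the list alone; adjusted p = 0.00485, and adjusted p = 0.543 with an estimated correlation), and the list gave 0.996 without the NZB library and had 0 genes past the test without any 1 heteroplasmic library. The heat shock and circadian lists were higher by camera with no member past the test, over all genes or over the list alone (adjusted p = 0.0259 and 0.0265, and adjusted p = 0.601 and 0.316 with an estimated correlation). Without the C57 library they gave 0.331 and 0.208, and the circadian list gave 0.0923 without the NZB library. With the length and GC trends removed the insulin, calcium and circadian lists gave adjusted p = 0.0800, 0.0731 and 0.0800, their medians were 0.14, 0.08 and 0.09, and 0 of their genes rose.

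Fabp3, the heart fatty acid binding protein, stood at -0.28 and was the 1 gene that fell in the PPAR alpha list (16 genes) and in the fatty acid oxidation list (25 genes), and the 1 adjusted over the list alone in each. These lists gave adjusted p = 0.00921 and 0.0496, and adjusted p = 0.330 and 0.593 with an estimated correlation. The PPAR alpha list gave 0.301 without the C57 library. The fatty acid oxidation list gave 0.0906 without the C57 library, 0.321 without the NZB library, and 0.0797, 0.0855, 0.0978, 0.0708 and 0.0673 without heteroplasmic libraries 1, 2, 6, 7 and 8, and 0.0707 with libraries 1 and 5 both omitted. Of 27 antioxidant genes 2 fell (10 fell and 1 rose adjusted over the list alone), including the superoxide dismutase Sod1 at -0.33 (adjusted p = 0.00294, and adjusted p = 0.330 with an estimated correlation; 0.219 without the C57 library). With the length and GC trends removed the antioxidant list gave adjusted p = 0.141 with 1 gene lower, and the fatty acid oxidation list 0.479 with 0 lower. Of 11 atrial markers Dkk3 fell at -1.03 (2 adjusted over the list alone; adjusted p = 0.0254, and adjusted p = 0.375 with an estimated correlation), and the list gave 0.158 without the C57 and 0.0782 without the NZB library.

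**Figure D3:**
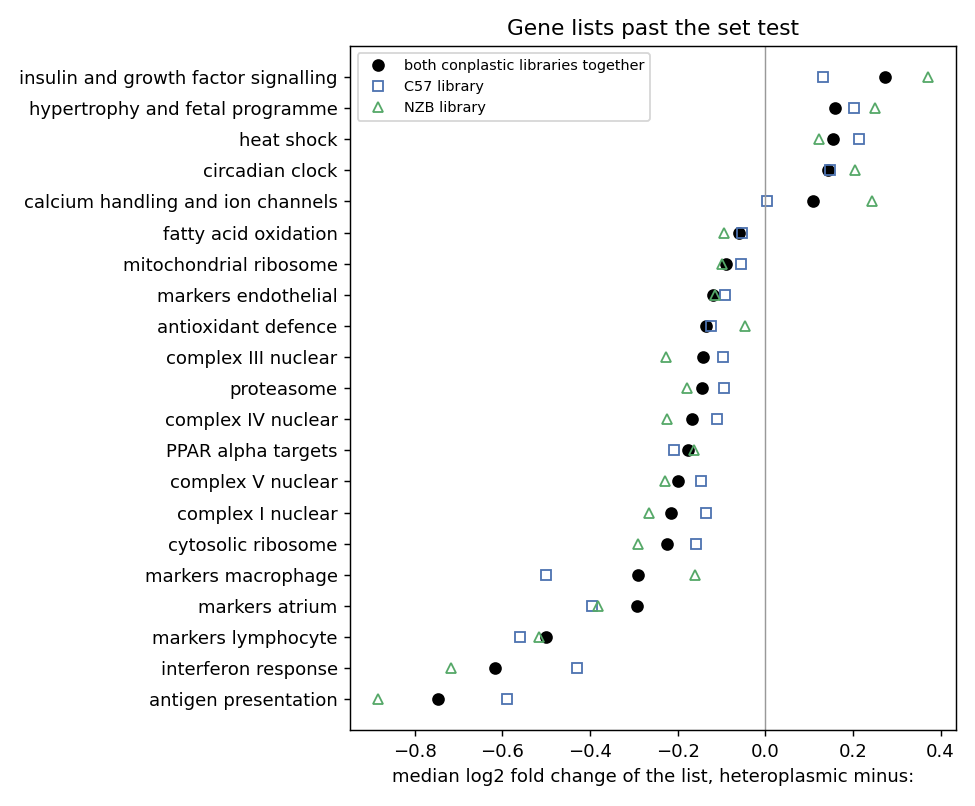
Median log2 fold change of the 21 gene lists past the set test, heteroplasmic minus both conplastic libraries together (filled circles), minus the C57 library (squares) and minus the NZB library (triangles). Among the filled circles the antigen-presentation list lies lowest at -0.75 and the insulin and growth factor list highest at 0.27.

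Among sarcomere genes 4 of 22 rose (5 rose and 1 fell adjusted over the list alone), among them Mybpc3, Ttn and Myom1, at 0.41, 0.40 and 0.27. The list itself did not pass (adjusted p = 0.143). Of its genes 2 rose without heteroplasmic library 2, 4, 5, 6, 7 or 8 and with libraries 1 and 5 both omitted, 1 rose without the NZB library, and 6 rose and 4 fell without the C57 library. With the length and GC trends removed 1 rose, and Ttn stood at 0.03. Lists of glycolysis (24 genes), inflammation (22 genes) and the integrated stress response (26 genes) had no member past the test, over all genes or over the list alone, and adjusted p = 0.481, 0.905 and 0.624. Myocd, a coactivator of cardiac and smooth muscle genes, was higher at 45.7 ± 5.48 CPM against 33.5 and 21.5 (log2 fold change 0.74 ± 0.17, adjusted p = 0.0388). Filip1, the retrovirus restriction gene Fv1, the flippase Atp8a2 and the cadherin Celsr1 rose by 0.73, 0.78, 0.77 and 0.74; with the trends removed these genes and Myocd missed the threshold. Dyrk2, Dock5, Fan1, Rrp12, Pggt1b and Zfp971 rose by 0.71, 0.66, 0.65, 0.64, 0.63 and 0.63. Pcdhgc4 stood at -1.10 and shares exons with other protocadherin gamma genes, which makes its count uncertain.

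Rps12, a ribosomal protein gene outside the ribosome list (chromosome 10, 23785183 to 23787275), had the largest rise among the named genes. It stood at 35.5 ± 7.11 CPM (SD, n = 8) against 5.99 in the C57 and 5.15 in the NZB library, a log2 fold change of 2.68 ± 0.27 (edgeR adjusted p = 0.00624). Without the NZB library its adjusted p was 0.0593. The pseudogene Rps12-ps3, named after its values were seen, stood at -0.77 ± 0.11 (74.4 CPM against 117 and 136), so the division of reads between the pair is uncertain.

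Over all genes, edgeR's quasi-likelihood test found 607 genes changed between heteroplasmic and conplastic hearts, of which 269 were higher and 338 lower. Most changes were small: 471 were under 1.5-fold, 8 of the higher and 49 of the lower genes reached 2-fold, and the median absolute log2 fold change was 0.38. For 1128 genes all 8 heteroplasmic libraries lay above both conplastic libraries and for 1400 below, 15.7% of the genes tested. A single gene would do so by chance in 4.44% of splits, but genes vary together, so the excess does not exclude chance. With the length and GC trends removed the numbers were 1037 above and 1030 below. The count was 42 without the NZB library, 2404 without the C57 library, and 328, 140, 208, 153, 269 and 342 without heteroplasmic libraries 2, 4, 5, 6, 7 and 8; of 59 named genes past the test, 3 (Ifit3, Rsad2 and Mybpc3) passed without the NZB library. The balance of directions turned by DESeq2 (823 higher and 605 lower), with 3 genotypes and the mean of C57 and NZB (1068 higher and 683 lower), without a low-count filter (270 higher and 222 lower) and without the C57 library (1583 higher and 821 lower). The count was 1428 by DESeq2, and 184 with the length and GC trends removed and 110 without heteroplasmic libraries 1 and 5, settings chosen after seeing the data.

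Of the 13 proteins encoded by mtDNA, 2 had higher transcripts in heteroplasmic hearts (4 adjusted over the list alone). Transcripts of mt-Nd5, a complex I subunit (mtDNA, 11742 to 13565), were at 22722 ± 1506 CPM (SD, n = 8) against 17263 in the C57 and 14138 in the NZB library, a log2 fold change of 0.53 ± 0.08 (edgeR adjusted p = 0.0120). Those of mt-Nd4l, another complex I subunit (9877 to 10173), rose by 0.42 ± 0.09 (adjusted p = 0.0289), and the gene overlaps mt-Nd4, so its share of reads is uncertain. For both genes all 8 heteroplasmic libraries lay above both conplastic libraries. The other 11 genes did not pass. Among them mt-Atp8 and mt-Nd2, at 0.21 and 0.18 (adjusted p = 0.0825 and 0.123), also had all 8 heteroplasmic libraries above both conplastic libraries, and mt-Co1 and mt-Cytb stood at 0.02 and -0.02. The list of 13 gave adjusted p = 0.135, and its median was 0.17 against the C57 and -0.06 against the NZB library. Without the NZB library the adjusted p was 0.0827 for mt-Nd5, 0.168 for mt-Nd4l and 0.00536 for the list. Without heteroplasmic library 4 the list gave adjusted p = 0.0386. For mt-Nd4l the adjusted p was 0.0540 without heteroplasmic library 6 and 0.0679 with libraries 1 and 5 both omitted. With the trends removed the adjusted p was 0.0271 for mt-Nd5, 0.0661 for mt-Nd4l and 2.42e-06 for the list, with mt-Nd4l at a log2 fold change of 0.60. That removal, fitted over all tested genes with a length, moved the list median from 0.04 to 0.20. Before it, these 13 genes took 35.2% of counts in the C57 library, 39.3% in the NZB library and 35.2% to 38.6% in the heteroplasmic libraries.

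**Figure D4:**
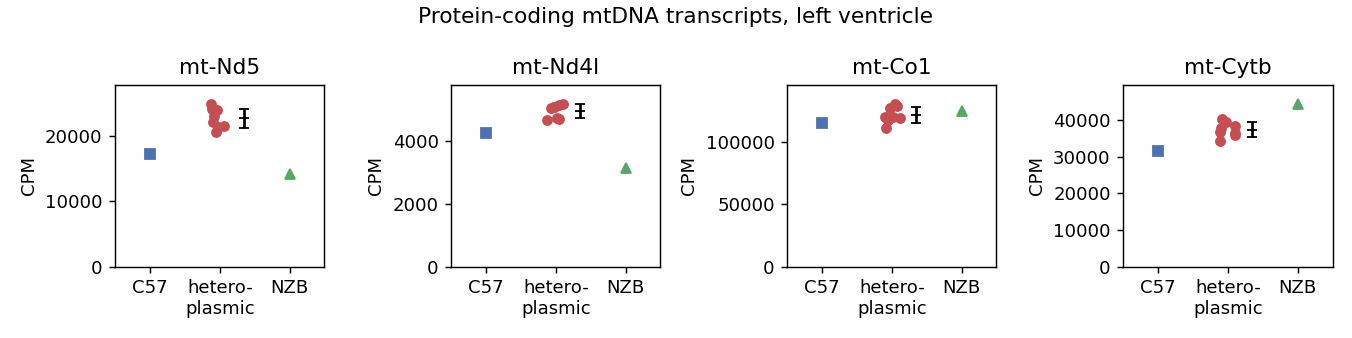
CPM of 4 mtDNA transcripts in each library (C57 square, heteroplasmic circles with mean and SD, NZB triangle; linear axes from 0). For mt-Nd5 and mt-Nd4l the 8 heteroplasmic libraries lie above both conplastic libraries, while for mt-Co1 and mt-Cytb their mean lies between them.

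Against the C57 library alone, heteroplasmic hearts had higher Myh7b, a myosin heavy chain gene, and lower Klf10, a growth-response transcription factor. Myh7b (chromosome 2, 155611212 to 155634307) stood at 93.0 ± 11.4 CPM (SD, n = 8) against 39.9 in the C57 library (log2 fold change 1.22, edgeR adjusted p = 0.0436), and Klf10 (chromosome 15, 38291463 to 38300706) at 8.04 ± 1.08 against 17.9 (-1.16, adjusted p = 0.0143). Bdh1, a ketone body enzyme, was at 67.8 ± 5.05 against 125 CPM (-0.89, adjusted p = 0.00190). The interferon-induced genes Rsad2 and Ifi27l2a were lower at -0.83 and -0.91, as was Mgst1, a glutathione transferase, at -0.80. The non-coding RNAs Firre and Airn were higher at 0.78 and 0.73, and Tmem131 and Metap1d at 0.61 and 0.60. In all 38 genes passed, 13 higher and 25 lower. The test treats the lone C57 library as varying like the heteroplasmic libraries. The count was 193, 20, 4, 17, 9 and 7 without heteroplasmic libraries 1 (106 higher and 87 lower), 2, 4, 5, 6 and 7, and 356 by DESeq2, 126 without a low-count filter, 9 by limma voom and 7 without robust dispersion.

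Against the NZB library alone, heteroplasmic hearts had higher Ppara, the fatty acid-sensing nuclear receptor, and lower interferon-induced GTPases. Ppara stood at 29.8 ± 1.46 CPM (SD, n = 8) against 8.17 in the NZB library (log2 fold change 1.87, edgeR adjusted p = 5.17e-07). The kinase gene Hipk2 (chromosome 6, 38694390 to 38876165) was at 71.2 ± 8.96 against 10.5 CPM (2.76, adjusted p = 9.63e-05), and the cytosolic nucleotidase Nt5c1a at 10.05 ± 1.63 against 1.88 (2.42, adjusted p = 0.000487). Pm20d2 was higher at 1.86 and Rps12 at 2.79. Igtp, Tgtp2, Gbp4, Iigp1 and Pcdhgc4 were lower at -1.81, -1.77, -1.57, -1.53 and -1.49. In all 2403 genes passed, 1540 higher and 863 lower. The lone library is again assumed to vary like the heteroplasmic libraries, and the contrast carried the length trend (rho = 0.359 across genes, against 0.136 for the C57 contrast). Whether the contrasts with C57 and with NZB differ was not tested.

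Between the NZB and C57 libraries, with no replicates and no test, 85 genes with a mean CPM of at least 5 differed by more than 2-fold and by more than the whole range of the heteroplasmic libraries. Of these 33 were higher and 52 lower in the NZB library. With a mean CPM of at least 1 the count was 227. Slc15a2, a peptide transporter (chromosome 16, 36750177 to 36784962), was at 17.1 CPM in the NZB and 0.632 in the C57 library, with heteroplasmic libraries from 0.990 to 10.99. Nr4a1, an immediate early nuclear receptor, was at 25.5 against 4.09, and Lsm7 at 9.76 against 2.99. Hipk2 (10.5 against 54.9), Plekhh1 (2.42 against 8.72) and Nt5c1a (1.88 against 6.59) were lower in the NZB library, as were the red cell genes Alas2 (11.4 against 39.6) and Hbb-bt (106 against 351).

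Genes that report sex and the nuclear background were read in each library. Ddx3y, Kdm5d, Uty and Eif2s3y of the Y chromosome were counted in every library, and Xist reached at most 33 counts. Nnt, a mitochondrial transhydrogenase truncated in some C57 lines, had 22259 to 78901 counts per library and a log2 fold change of -0.20 (adjusted p = 0.424). Mmrn1, which is deleted in the C57BL/6JOlaHsd line, had no counts in either conplastic library. Heteroplasmic library 1 held 85 counts of Mmrn1, library 5 held 6 and library 2 held 2.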

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

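The tests on leukocyte and lymphocyte markers, on the length and GC correction, on complexes I and V apart from complexes III and IV, and on the mtDNA genes were chosen after the results were seen.

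Of 109 measures over the 8 heteroplasmic libraries, 7 had a library far from the others by Dixon's ratio of gap to range, which chance gives for about 1 group in 20. In library 8 S100a8 was at 9.08 CPM against 0.685 to 2.73 in the others (ratio 0.756), S100a9 at 12.6 against 0.965 to 4.29 (0.713) and Ifi27l2a at 8.66 against 5.65 to 7.01 (0.547). In library 1 Mmrn1 was at 2.41 CPM against 0 to 0.0919 (0.962) and Pm20d2 at 24.3 against 18.6 to 20.7 (0.631). Iigp1 was at 61.96 CPM in library 3 against 24.99 to 42.1 (0.538). The mtDNA share of counts was 35.9985% in library 4 against 37.9% to 39.3% (0.560). S100a8 and S100a9 were added to these measures after their values were seen.

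For the lower interferon and antigen-presentation genes, transcript length and GC as the whole cause are argued against by a median of -0.61 over the 45 genes with the trends removed, against -0.63 before. List by list the shift was larger, from -0.62 to -0.54 for interferon and from -0.75 to -0.66 for antigen presentation. Of the 45 splits of the libraries into 8 and 2, 1, the real one, gave a median as far from 0 (-0.63, against 0.45 in size for the highest other). That is the smallest share that 45 splits can give, and the pattern was picked from these same libraries, so chance is not excluded. A difference between single animals stays open too. Each conplastic genotype has 1 library, and the labels do not say that the 8 are separate animals. The 38 macrophage, lymphocyte and neutrophil markers had a median of -0.34 and a lower quartile of -0.51, above the lists' median, and a first criterion excluded fewer leukocytes on that ground, but against the C57 library alone their median was -0.43 and lower quartile -0.67, beside -0.49 for the lists. Against the NZB library the markers stood at -0.19 (lower quartile -0.49) beside -0.78, so the exclusion holds against 1 of the conplastic libraries only, and under a criterion added after these values were seen the explanations cannot be told apart. The 17 lymphocyte markers alone had a median of -0.50 and quartiles of -0.92 and -0.39, which reach the lists' median, so fewer lymphocytes cannot be told apart from a lower interferon response either; both may follow mtDNA genotype, but differences of colony, housing or infection between the strains were not tested and stay open.

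For the short-transcript lists, 0.01% of 10000 random lists matched on length and expression, the smallest share they can give, had a median as low as the cytosolic ribosome, and 0.01% as low as complexes I and V. The random genes were drawn one by one, while genes of these lists vary together. Their estimated correlation was 0.46 for the cytosolic ribosome, 0.39 for complex I and 0.21 for complex V. The shares may therefore be too small, and length as the whole cause is not excluded there. The medians of the cytosolic ribosome and complexes I and V went from -0.22, -0.21 and -0.20 to -0.10, -0.08 and -0.09 with the trends removed. For complexes III and IV the share was 37.5%, so length could account for them. A bound of 5% set in advance would have excluded length for the proteasome (2.04%) and for complexes I, III, IV and V pooled (0.01%), but a further criterion, passing camera with the trends removed, was added after those shares were seen, because the proteasome median went from -0.14 to -0.02 with the trends removed (adjusted p = 0.320) and complexes III and IV did not stand apart from matched lists. For the proteasome and the pooled complexes, length and a change of expression cannot be told apart under that added criterion. For the pooled complexes it took the largest camera adjusted p of the single lists, 0.408 for complex IV, while complexes I and V gave 0.000185 and 0.00225. Of the 45 splits 1, the real one, gave a pooled median as far from 0 (-0.19, against 0.13 in size for the highest other). As above, this leaves chance and a difference between single animals open, while RNA quality and mtDNA genotype stay open and untested.

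For mt-Nd5 and mt-Nd4l, loss of NZB-variant reads in mapping would put the heteroplasmic mean between the conplastic libraries, and it lay above the higher, the C57 library, by 3.63 and 3.35 heteroplasmic SDs. A first criterion excluded mapping loss on that ground, but it restates the pattern, and under the added criterion of passing against that library alone neither gene passed (adjusted p = 0.0769 and 0.168), so mapping loss and a change of expression cannot be told apart. A rise of all mtDNA transcripts would move the other 11 genes as far, and their median was 0.025 (upper quartile 0.07), or 0.18 with the trends removed and 0.14 without the NZB library. In the fit without the NZB library mt-Nd4l itself stood at 0.23, close to the upper quartile of 0.21 for the others, and neither gene passed. Read sharing between mt-Nd4l and the overlapping mt-Nd4 was not tested, and each conplastic level rests on a single library, so a difference of that library stays open beside mtDNA genotype.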

How the results depend on the processing

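The removal of length and GC trends and the omission of heteroplasmic libraries 1 and 5 were chosen after the results were seen. No paired analysis was possible because replicate numbers exist only in the heteroplasmic group. For heteroplasmic versus conplastic, 607 genes (269 higher, 338 lower) became 1751 with 3 genotypes and the mean of C57 and NZB (1068 and 683), 1428 by DESeq2 (823 and 605), 5 in a test against a 1.5-fold change, 184 with the trends removed (65 and 119, 155 of them among the 607) and 110 without libraries 1 and 5 (45 and 65, 105 among the 607). Leaving out a single library gave 42 (NZB, 14 and 28, 15 among the 607) to 2404 (C57, 1583 and 821, 514 among the 607), with 328, 140, 208, 153, 269 and 342 without heteroplasmic libraries 2, 4, 5, 6, 7 and 8. DESeq2's size factors gave 290 higher and 294 lower genes, no filter 270 and 222. Of 45 splits of the libraries into 8 and 2, 1, the real one, called as many genes and the highest other called 39. That is the smallest share that 45 splits can give, so it does not exclude chance. With 1 library per conplastic genotype, a difference between single animals stays open whether or not the 8 are separate animals. Against C57, 38 genes became 126 without a filter, 7 without robust dispersion, 9 by voom and 356 by DESeq2, and 193, 20, 4, 17, 9 and 7 without heteroplasmic libraries 1, 2, 4, 5, 6 and 7. Against NZB, 2403 genes ranged from 1730 to 2778 over the alternatives run. Genes past the size rule went from 85 to 227 with a mean CPM of at least 1. The number of lists past camera, 21, became 0 with an estimated correlation, and 13 (without C57) to 22 (without heteroplasmic library 4) with a library left out. Of the 21 themselves, 13 were kept without C57, 14 were kept, 6 lost and 1 turned without NZB, 20 or 21 were kept without each heteroplasmic library, and 12 were kept and 9 lost with the trends removed. With libraries 1 and 5 omitted, 9 interferon and 7 antigen-presentation genes passed, and at most 2 in any other list. The list of calcium handling and ion channels had adjusted p = 1.40e-05 without the C57 library and turned direction by camera without the NZB library (adjusted p = 0.996). Of 79 calls of named genes, DESeq2 kept 78, voom 72 and the removal of trends 46, leaving out heteroplasmic libraries 1 to 8 in turn kept 74, 57, 73, 38, 51, 40, 54 and 67, and of 59 for the main comparison 3 were kept without the NZB library, 54 without the C57 library and 22 without libraries 1 and 5, with no call reversed. The cause was not tested for any of these changes. The C57 library had the fewest counts, 29380653, and the effect of depth was not tested.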

Other observations

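The comparisons of single heteroplasmic libraries were chosen after the results were seen. Those of the NZB and the C57 library repeat the fits above that left out the other conplastic library, and are not a further result. Tested alone against the 8 heteroplasmic libraries the NZB library gave 2404 genes and the C57 library 42, while each heteroplasmic library against the other 7 gave 0 to 7 by edgeR. Each of these tests has a lone library in 1 arm, which is assumed to vary like the others, so the counts describe these libraries. Among the 3216 genes with the longest transcripts 186 rose and 14 fell in heteroplasmic against conplastic hearts, and among the 3216 with the shortest 13 rose and 170 fell.

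Of 9 red blood cell markers none passed the test, and their median was -0.92 against the C57 library and 0.77 against the NZB library. Hba-a1, which has a near-identical copy and is uncertain for that reason, was at 586 CPM in the C57, 268 in the NZB and 300 ± 77.1 CPM (SD, n = 8) in the heteroplasmic libraries. Albumin transcripts (Alb), named after their values were seen, were at 1.86 CPM in the C57, 2.596 in the NZB and 0.267 ± 0.243 in the heteroplasmic libraries (log2 fold change -3.11 ± 0.55, adjusted p = 0.0218).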
